A study of Mus musculus with 6 samples.

How the data were processed

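Polyadenylated RNA from mouse brain was sequenced at postnatal day 14 in 3 wild-type (WT) samples and 3 samples labelled as knockouts of PRMT5 driven by Olig2-Cre (KO). Per the labels' protocols, RNA was extracted with Trizol, libraries followed the Illumina TruSeq mRNA protocol, and reads were 150 bp paired-end. Per the submitters' processing notes, FastQC 0.11.2, Trimmomatic 0.32, STAR 2.3.0e, featureCounts 1.5.0 and DESeq2 were used with the mm10 build. The deposited counts are labelled as counts per gene over exons of UCSC known genes. The strand setting of the counting and the treatment of reads mapping to several places were not given in the sources used here. Reads of overlapping genes, and of a gene and its antisense partner, are therefore treated as possibly shared.

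The authors deposited a table of whole-number read counts per gene and a table of normalized signal, each with 31276 gene symbols in 6 columns. The deposited normalized signal equalled the count divided by 1 factor per library, to within 1e-14, and those factors equalled DESeq2's median-of-ratios size factors. Every column name matched the label of 1 sample. The total count per library ran from 15089140 to 16872925, and 9145 symbols had no count in any library. Within a group, pairs of libraries differed by 6.75 to 27.41 times the chi-square expected from counting noise alone, over genes with at least 20 counts in the pair, so no library was treated as a duplicate of another.

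All tests started from the deposited counts, in R 4.3.3. Genes were filtered with filterByExpr on the group, which left 16592 genes, and library composition was scaled with TMM factors. KO was compared with WT with edgeR 4.0.16 (glmQLFit and glmQLFTest), with 4 residual degrees of freedom and no covariate. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called, and log2 fold changes are KO over WT with their standard error (SE). The common biological coefficient of variation was 0.15. Expression per library is given as CPM (edgeR cpm function, on TMM-scaled totals), computed here.

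Before the data were examined, 31 gene lists were fixed. They covered stages of the oligodendrocyte lineage, cholesterol synthesis, p53 targets, proliferation, other glia, neuron classes, vessels, meninges and other cell types that a brain dissection holds. Lists with at least 3 tested members were compared with all other genes with camera (limma 3.58.1) on log2 CPM with a prior count of 2, at a preset inter-gene correlation of 0.01, and adjusted over the 31 lists. The test was repeated with a correlation estimated per list. The lists were also tested with fry, which asks a different question and does not compare the members with other genes. Its directional form asks whether the members shifted up or down together, and its mixed form allows changes in either direction. With the estimated correlation only the lists of lineage transcription factors, precursors and newly formed oligodendrocytes stayed called. Older symbols were matched through a RefSeq table, and coordinates are from GENCODE release M21 on mm10, in which 22559 of the symbols were found.

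The genes named below follow a rule fixed at the same time. It took Prmt5, Olig2, Pdgfra, Mbp and Gfap, then the 8 largest rises and the 8 largest falls among called genes with a mean of at least 1 CPM and group ranges that did not overlap. It also took the 3 members with the smallest p of each of the 11 primary lists, and the leading member of each other list where that member was called. Predicted genes were counted and not named, and not every other gene that the rule took is named. Any other gene named was chosen after its values were seen.

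Both groups carry replicate numbers 1 to 3 in the labels, with no statement of what a number stands for. Deviations from the group means correlated at 0.351, 0.334 and 0.177 between the same-numbered samples, above the limit of 0.1 set beforehand, so the numbers were taken as pairs. The pairing comes from the data and not from the labels. Without the genes that followed cerebellar transcripts these correlations were 0.089, 0.134 and 0.247, the first of them under that limit. The fit with the replicate number as a block has 2 residual degrees of freedom and is given beside a result where it changed the call.

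The alternatives fixed beforehand were 17 fits at gene level and 2 further list tests. They comprised 3 other scalings, 2 other filters, DESeq2 1.42.0, limma-voom, limma on log2 of the deposited normalized signal plus 1, a robust spread, thinning to the smallest library, the replicate block, and leaving out each of the 6 libraries. After the data were seen, 9 more were added. These were a term for cerebellar transcripts (Gabra6 above 5 CPM) with and without the block, a term for sex (Xist above 5 CPM), the libraries with and without cerebellar transcripts alone, and offsets adjusted per library for GC content or for exon length by loess with a span of 0.5, with and without the block. GC content and length were known for 88.0% of tested genes. No list test was run with DESeq2 or within the libraries with or without cerebellar transcripts.

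The tests were checked on simulated counts with 200 changed genes, drawn from the means, library sizes and spread of these samples, for KO against WT. Over 16391 genes, the edgeR test recovered 34.3% of genes changed 1.5-fold, 80.6% of those changed 2-fold and 90.5% of those changed 4-fold, and 7.59% of its calls were false. The false share was 9.46% with the replicate block (16402 genes) and 10.3% with DESeq2 (16592 genes), the fits that called more genes in the real data. For the block alone, a random shift per gene and replicate number, not taken from these samples, was added to the simulated means. Its false share therefore holds for samples that truly pair, and not for replicate numbers without meaning. The list test called 0 of 20 unchanged lists at an unadjusted p under 0.05. The simulated genes varied independently of each other, so this check does not cover lists whose members vary together. Figures were drawn with matplotlib 3.10.9.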

Results

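RNA from mouse brain at postnatal day 14, when myelination is under way, was sequenced in 3 WT and 3 KO samples. In the KO, the gene for PRMT5, an arginine methyltransferase that modifies histones and splicing proteins, was targeted with Cre recombinase expressed under control of Olig2, a transcription factor gene of the oligodendrocyte lineage. The comparison asks how brain gene expression differs when Prmt5 is targeted in cells that have expressed Olig2. The WT libraries held 15919292, 15219817 and 16872925 counts and the KO libraries 16365802, 16108457 and 15089140, for replicates 1 to 3. The labels do not say whether the samples of a group came from separate animals. Xist, transcribed in females, stood at 0.25, 509.11 and 0.24 CPM in WT replicates 1 to 3. In KO replicates 1 to 3 it stood at 634, 603.35 and 0.25 CPM. These values argue against all samples of a group coming from the same animal. Whether samples of the same sex did is not known. The p-values measure the spread between these samples, part of which can be technical.

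The targeted gene itself was measured first. Prmt5 stood at 91.0 ± 0.751 CPM in WT and 72.7 ± 7.66 CPM in KO (SD, n = 3), a log2 fold change of -0.32 (SE 0.0950), and the KO samples were all below the WT samples. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment its adjusted p was 0.232, and 0.0379 with the replicate block. Brain tissue holds many cells outside the Olig2 lineage, and reads from exons outside a deleted segment are still counted. Of the list of 9 arginine methyltransferase genes, 0 were called by edgeR and 0 by DESeq2, and 1, Prmt5, had an unadjusted p under 0.05; adjusted over the list alone the count was also 0. The list did not stand apart from other genes (median log2 fold change 0.01, camera adjusted p = 0.786).

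Genes of oligodendrocytes and myelin were lower in KO brain, and genes of meningeal fibroblasts were higher. Mbp, which encodes myelin basic protein, fell from 4601 ± 893 CPM in WT to 688.7 ± 252 CPM in KO (SD, n = 3), and Sox10, a transcription factor of the lineage, from 105.4 ± 4.39 to 29.2 ± 2.53 CPM. Col3a1, a fibrillar collagen gene, rose from 23.5 ± 4.46 to 82.0 ± 18.0 CPM. Of 16592 genes tested, 199 were called, 159 lower and 40 higher in KO, and 106 of them by at least 2-fold (90 lower, 16 higher). At an unadjusted p under 0.05 there were 1605 genes. The WT and KO ranges did not overlap for all 199 called genes, and for 16% of tested genes against the 10% that chance gives. With the replicate block 566 genes were called (171 higher, 395 lower), which included all 199 in the same direction. DESeq2 called 315 (74 higher, 241 lower). Without WT replicate 1, 2 or 3 the count was 126, 110 or 100, and without KO replicate 1 or 3 it was 305 or 132.

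**Figure D1:**
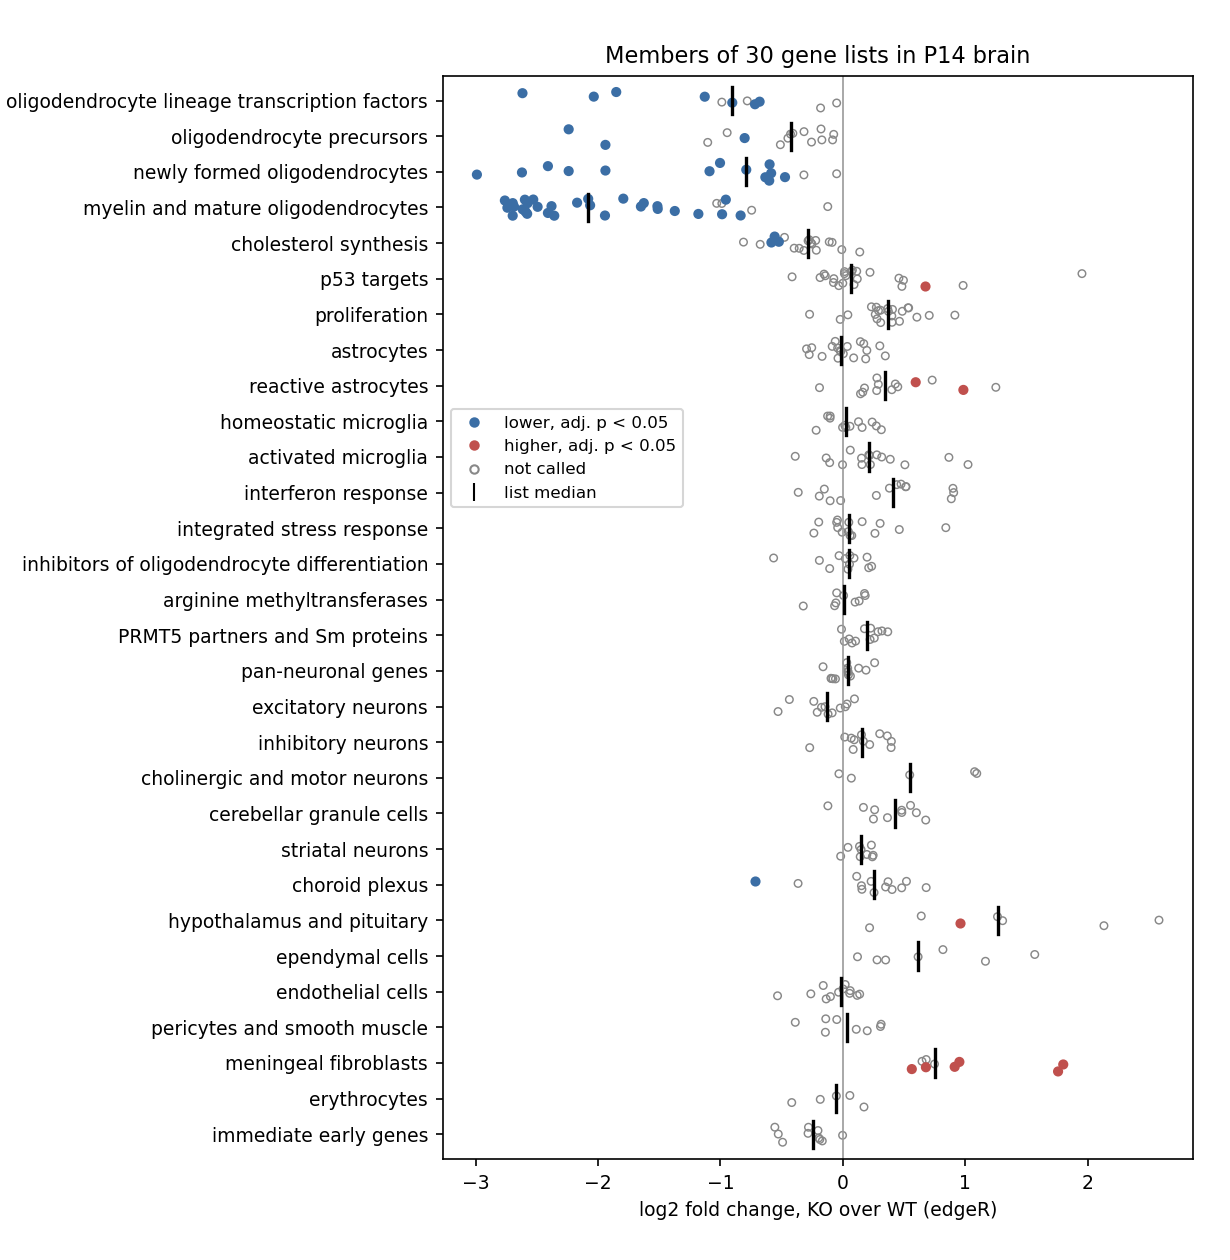
Log2 fold change (KO over WT, edgeR, horizontal axis) of each tested member of 30 gene lists (rows); filled points are called lower (blue) or higher (red), open points are not called, and black bars are list medians. The myelin list has its median at -2.08, and the meningeal fibroblast list at 0.75.

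The libraries also differed in dissection and sex. Gabra6, a receptor gene of cerebellar granule cells, stood at 63.84, 80.03 and 22.11 CPM in WT replicate 1, KO replicate 1 and KO replicate 3, and at 0 in WT replicates 2 and 3 and KO replicate 2. With genotype in the model, 121 genes were called between libraries with and without these transcripts. With this difference as a term in the fit, 229 genes were called for genotype (46 higher, 183 lower), of which 186 were among the 199. Among the libraries without cerebellar transcripts alone (KO replicate 2 against WT replicates 2 and 3), 1254 genes were called, and among those with them (KO replicates 1 and 3 against WT replicate 1), 162. In both, the lone sample is assumed to vary like the others, so these counts say nothing about the spread within its group. Xist, transcribed in females, was abundant in WT replicate 2 and KO replicates 1 and 2 (509.1, 634.0 and 603.4 CPM) and at most 0.25 CPM in the others, so the sexes were unequal between groups. With sex as a term 129 genes were called (15 higher). The 6 sex-linked genes as a list were not called (camera adjusted p = 0.626), with 0 members called by edgeR, by DESeq2, over the list alone or at an unadjusted p under 0.05; 1, Tsix, was called with the replicate block, and DESeq2 gave no adjusted p for 4 of them. Shorter genes lay higher in KO replicates 2 and 3, and more so in replicate 3. The correlation of deviations from the mean of all libraries with exonic length, across genes, was -0.137 and -0.412 in these libraries, and 0.193 in KO replicate 1, within the WT range of 0.108 to 0.222. For KO against WT, the median log2 fold change was 0.10 in the 3652 genes with the shortest exonic length and -0.07 in the 3650 with the longest, with a Spearman correlation of -0.276 across genes, which are not independent replicates.

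Transcription factors of the oligodendrocyte lineage were lower in KO. Of 11 tested, 7 fell (9 adjusted over the list alone, and 9 with the replicate block), with a list median of -0.90. Myrf, which drives myelin gene transcription, fell by 2.62 on the log2 scale (SE 0.235), and Sox10 by 1.85 (SE 0.0972). Olig2 went from 51.5 ± 4.09 to 27.5 ± 3.55 CPM (SD, n = 3), a log2 fold change of -0.90 (SE 0.120) and a BH-adjusted p of 0.00329 in edgeR's quasi-likelihood test, and the neighbouring Olig1 fell by 0.72 (SE 0.0801). The list was called by camera (adjusted p = 2.12e-19) and also with an estimated correlation (adjusted p = 0.0233).

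Markers of oligodendrocyte precursors, the dividing cells that give rise to oligodendrocytes, were lower by a smaller amount. Of 15 tested, 3 fell (9 adjusted over the list alone), with a median log2 fold change of -0.43, and 8 with the replicate block. Pdgfra, the receptor that marks these cells, went from 90.8 ± 1.83 to 52.1 ± 3.43 CPM (SD, n = 3), a log2 fold change of -0.80 (SE 0.0877, BH-adjusted p = 0.000996 in edgeR's quasi-likelihood test). The other members that fell, Gpr17 (-2.24) and Neu4 (-1.94), are on the list of newly formed oligodendrocytes too. Of the 15 genes of newly formed oligodendrocytes, 13 fell (14 adjusted over the list alone), with a median of -0.79. Among them were Bcas1, a marker of early myelinating cells, at -2.41 (SE 0.155), and Gpr17, a receptor of cells committed to differentiation (SE 0.1097). Reads at Gpr17 may be shared with Lims2, and those at Bcas1 with Bcas1os1 and Bcas1os2, which overlap them on the opposite strand. Both lists were called by camera (adjusted p = 2.08e-12 for precursors and 4.15e-31 for newly formed cells) and with an estimated correlation (adjusted p = 0.0228 and 0.00844).

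Myelin genes had the largest median difference of any list in the fit of all libraries without covariates. Of 33 tested, 29 fell and 31 did when adjusted over the list alone, all 33 had negative values, and the median was -2.08, a 4.23-fold lower level. Mbp was 6.68-fold lower (log2 fold change -2.74, SE 0.241, BH-adjusted p = 0.000201 in edgeR's quasi-likelihood test). The log2 fold change of Mbp was -3.36 among libraries with cerebellar transcripts and -2.08 among those without, and the list median -2.53 and -1.61, so the size of the fall depended on the libraries compared. Mog, a surface protein of myelin, fell by 2.70 (SE 0.279) and Fa2h, which makes hydroxylated myelin lipids, by 2.36 (SE 0.138). Of genes outside the lists, the calcium-sensing receptor gene Casr (-2.89), Nipal4 (-2.74) and the semaphorin receptor gene Plxnb3 (-2.72) were among the 8 largest falls, with Tmem125 (-2.70), a myelin list member. The list was called by camera (adjusted p = 1.59e-74), and it had an adjusted p = 0.0530 with an estimated correlation. With a robust estimate of the spread the calls of Mog and Plxnb3 ended, with edgeR adjusted p (Benjamini-Hochberg) of 0.0622 and 0.111. In all, 49 of the 159 genes that fell were among the 69 tested genes of these oligodendrocyte lists, and 106 were on no list.

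**Figure D2:**
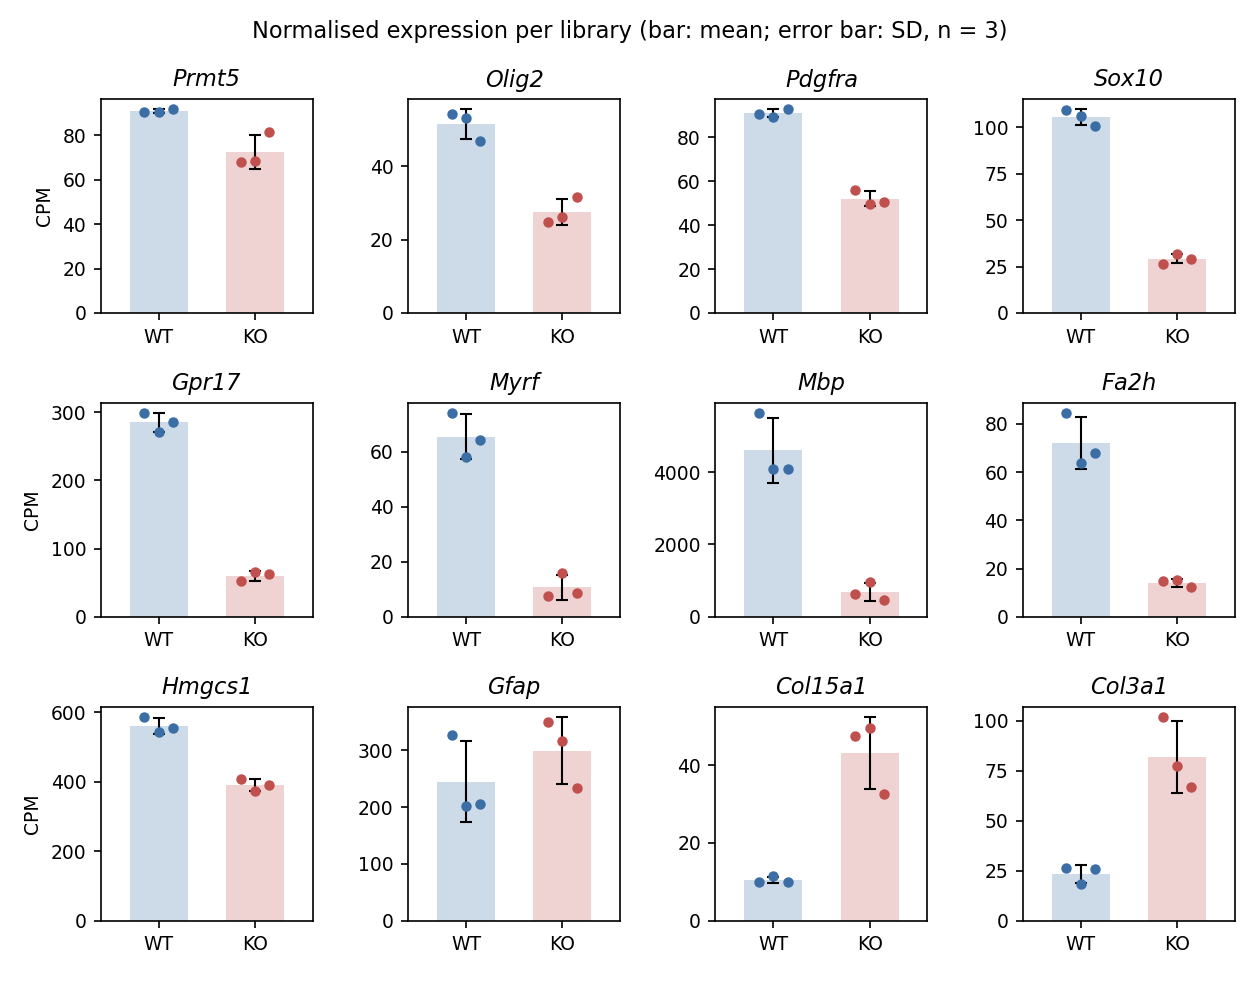
Expression of 12 genes in CPM (vertical axis, linear from 0) in WT (blue) and KO (red); points are libraries, bars means and error bars SD (n = 3). Mbp, Sox10 and Gpr17 have every KO library below every WT library, while Gfap overlaps between the groups and Col3a1 is higher in every KO library.

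Genes of cholesterol synthesis, a pathway that myelin growth relies on, were lower by less than myelin genes. Of 19 tested, 18 had negative values and 3 fell, with a list median of -0.28; adjusted over the list alone 13 fell, and with the replicate block 7. Hmgcs1, which acts early in the pathway, went from 560.8 ± 22.6 to 390.4 ± 17.1 CPM (SD, n = 3), a log2 fold change of -0.52 (SE 0.0898). Cyp51, a sterol demethylase whose reads may be shared with Akap9, fell by 0.56 (SE 0.107). Their BH-adjusted p in edgeR's quasi-likelihood test were 0.0172 and 0.0321, and both calls were lost without WT replicate 1, 2 or 3 or KO replicate 2 (adjusted p of 0.0632, 0.0766, 0.0940 and 0.0810 for Hmgcs1). The list was called by camera (adjusted p = 3.78e-12), and it had an adjusted p = 0.0840 with an estimated correlation.

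Genes of meningeal fibroblasts were higher in KO. Of 9 meningeal fibroblast genes, 6 rose and all 9 did when adjusted over the list alone or with the replicate block, with a median log2 fold change of 0.75. Col3a1 rose by 1.80 (SE 0.175, BH-adjusted p = 0.000368 in edgeR's quasi-likelihood test) and Lum, a proteoglycan of collagen fibrils, by 1.76 (SE 0.234). The largest rises among called genes with a mean of at least 1 CPM were Col13a1 (4.93-fold), a transmembrane collagen, Tgfbi (4.72-fold), a matrix protein gene induced by TGF-beta, Col15a1 (4.12-fold), a collagen of basement membranes, and Lama1 (3.99-fold), a laminin chain. Tbx18 (1.91), a transcription factor gene of mesenchymal and mural cells, and Tlr12 (1.79), a Toll-like receptor gene, were called with all libraries. Without WT replicate 2 or 3 or KO replicate 2 the edgeR BH-adjusted p of Tbx18 was 0.0863, 0.0934 or 0.0721, and that of Tlr12 ran from 0.0682 to 0.209 without each library in turn. The meningeal list was called by camera (adjusted p = 8.96e-17), and it had an adjusted p = 0.0530 with an estimated correlation. Genes of endothelial cells (median -0.02, camera adjusted p = 0.503) and of pericytes and smooth muscle (median 0.03, camera adjusted p = 0.579) did not stand apart. Of these 12 and 8 genes, 0 were called by edgeR, by DESeq2 or over the list alone, and 0 and 3 had an unadjusted p under 0.05.

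The p53 target list was not called (median 0.07, camera adjusted p = 0.0764). Of its 23 tested members 1 rose, Ephx1, an epoxide hydrolase gene (log2 fold change 0.67, SE 0.136, BH-adjusted p = 0.0444 in edgeR's quasi-likelihood test), and 3 did when adjusted over the list alone or with the replicate block. With the cerebellum term the adjusted p of Ephx1 was 0.0666 in the edgeR test (Benjamini-Hochberg), with length-adjusted offsets 0.0692, and without each library in turn 0.0537 to 0.229. Cdkn1a, which encodes the cell cycle inhibitor p21, had a value of 0.50 (SE 0.112) with an edgeR BH-adjusted p of 0.0777 and of 0.0153 with the replicate block, and Eda2r, a death receptor family gene, 1.95 (SE 0.515) with 0.155 and 0.0216. DESeq2 called Cdkn1a as well (BH-adjusted p = 0.0231). In the proliferation list, 20 of 22 genes had positive values and the median was 0.37, or 0.23 with the cerebellum term (camera adjusted p = 0.0014). The list was called by camera (adjusted p = 1.11e-05), and it had an adjusted p = 0.277 with an estimated correlation. Of the 22 genes, 0 were called by edgeR, by DESeq2 or over the list alone, and 5 had an unadjusted p under 0.05. Aurka, a mitotic kinase gene, had a value of 0.92 (SE 0.246), Ccna2, a cyclin gene, 0.37 (SE 0.118), and Rrm2, which is needed for nucleotide synthesis, 0.605 (SE 0.220).

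Astrocyte genes did not differ as a group. The median of 19 genes was -0.02, against a mean of 0.01 and an upward camera direction (adjusted p = 0.750). Of these genes 0 were called by edgeR, by DESeq2 or over the list alone, and 1 was called with the replicate block (Fabp7, a fatty acid binding protein gene), and 1 had an unadjusted p under 0.05, the glutamate transporter gene Slc1a2 (-0.30, SE 0.112). Cldn10 (0.30, SE 0.142) and Mlc1 (0.20, SE 0.0934) came next by p. Of 14 genes linked to reactive astrocytes, 2 rose and 3 did when adjusted over the list alone or with the replicate block, with a median of 0.35. These were the complement gene C4b (0.98, SE 0.187, BH-adjusted p = 0.0308 in edgeR's quasi-likelihood test) and Vim, an intermediate filament gene (0.60, SE 0.122, 0.0457). Both are also expressed outside astrocytes. Their calls were lost without WT replicate 2 or 3 or KO replicate 2 or 3, among others, at an edgeR BH-adjusted p of up to 0.172 for C4b and 0.284 for Vim, and without KO replicate 1 for Vim (0.0738) or WT replicate 1 for C4b (0.0542). Emp1, a membrane protein gene, had a value of 1.25 (SE 0.329) with an edgeR BH-adjusted p of 0.155, and of 0.00739 with the replicate block. DESeq2 (BH-adjusted p = 0.0277) and edgeR without a filter on low counts (BH-adjusted p = 0.0425) called Emp1 too. Gfap, the main filament gene of reactive astrocytes, stood at 244.9 ± 70.9 CPM in WT and 299.4 ± 59.3 CPM in KO (SD, n = 3), with overlapping ranges (log2 fold change 0.29, SE 0.194, edgeR BH-adjusted p = 0.668). Gfap was higher in KO in each same-numbered pair (326.8 and 348.9, 202.5 and 315.7, 205.3 and 233.7 CPM). With the replicate block alone it was not called (log2 fold change 0.306, edgeR BH-adjusted p = 0.096). With cerebellum term and replicate block together it was called (log2 fold change 0.37, edgeR BH-adjusted p = 0.0118). Only pair 3 differs in cerebellar transcripts, so the latter fit takes the genotype difference from pairs 1 and 2 alone. The reactive list was called by camera (adjusted p = 7.69e-06), and it had an adjusted p = 0.153 with an estimated correlation.

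Genes of homeostatic microglia did not stand apart (13 genes, median 0.02, camera adjusted p = 0.503, and 0.0431 with the cerebellum term). Gpr34 (0.31, SE 0.168), P2ry13 (0.24, SE 0.138) and Sall1 (-0.22, SE 0.147) had the smallest p, and 0 of the 13 were called by edgeR, by DESeq2, over the list alone or at an unadjusted p under 0.05. For 16 genes of activated microglia the median was 0.22 and camera called the list (adjusted p = 0.00862), with an adjusted p = 0.145 with an estimated correlation and 0.101 with length-adjusted offsets. Spp1, osteopontin, had a value of 0.87 (SE 0.281) and an edgeR BH-adjusted p of 0.295, and 0.00336 with the replicate block; Apoe, a lipid carrier also made by astrocytes, 0.28 (SE 0.0907), 0.299 and 0.0427. Lgals3 had a value of 1.02 (SE 0.369). Of the 16 genes 0 were called by edgeR or over the list alone, 1 by DESeq2, Apoe, and 4 had an unadjusted p under 0.05. The 14 interferon response genes had a median of 0.41 and were called by camera (adjusted p = 0.0410), with an adjusted p = 0.241 with an estimated correlation and 0.0536 with the replicate block. That call was also lost without WT replicate 2 (0.0576), WT replicate 3 (0.103) or KO replicate 3 (0.134), and 0 members were called by edgeR, by DESeq2 or over the list alone, with 4 at an unadjusted p under 0.05. The list call was lost as well with upper-quartile factors (0.0678), library totals (0.0683), no filter (0.119), the cerebellum term (0.0925) and length-adjusted offsets (0.113).

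Several lists tied to brain regions or fluid-lined surfaces leaned upward in KO. Of 7 tested genes of hypothalamus and pituitary, Trh, a releasing hormone gene, rose (0.95, SE 0.194, BH-adjusted p = 0.0438 in edgeR's quasi-likelihood test), 5 were higher when adjusted over the list alone and 3 with the replicate block, and the median was 1.26. The call of Trh was lost without any WT replicate or without KO replicate 2 or 3 (edgeR BH-adjusted p of 0.116 to 0.256). Of 7 ependymal genes, 4 were higher when adjusted over the list alone, 0 over all genes in edgeR, 1 with the replicate block and 1 in DESeq2, with 4 at an unadjusted p under 0.05 and a median of 0.61. Camera called both (adjusted p = 5.44e-07 for hypothalamus and pituitary and 8.11e-05 for ependymal cells), with adjusted p = 0.0840 and 0.153 with an estimated correlation. Among 13 choroid plexus genes the median was 0.25 and the list was not called (camera adjusted p = 0.142), though it was with the cerebellum term (0.0111). Its member Enpp2, which encodes autotaxin and is also expressed by oligodendrocytes, fell (-0.71, SE 0.148, edgeR BH-adjusted p = 0.0482, and 0.0506 with the cerebellum term), the only member called over all genes or over the list alone; Ttr was also called, higher, with the replicate block. Without WT replicate 3 its edgeR BH-adjusted p was 0.256, and without WT replicate 1 or 2 or KO replicate 2 or 3 it was 0.113, 0.0654, 0.0853 or 0.106.

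Lists of neuron markers went in different directions. Pan-neuronal genes had a median of 0.04 (14 genes, camera adjusted p = 0.750). Excitatory neuron genes had a median of -0.13 (12 genes) and were called by camera (adjusted p = 0.0255), with an adjusted p = 0.415 with an estimated correlation, 0.226 with the cerebellum term and 0.0760 with length-adjusted offsets. That call was also lost without KO replicate 1 (0.166), WT replicate 2 (0.155) or WT replicate 3 (0.0819). Inhibitory neuron genes had a median of 0.16 (12 genes, camera adjusted p = 0.0771, 0.00763 with the replicate block and 0.00034 with the cerebellum term) and striatal neuron genes of 0.15 (9 genes, camera adjusted p = 0.0764, 0.0200 with the replicate block and 3.81e-05 with the cerebellum term). Cholinergic and motor neuron genes had a median of 0.55 (5 genes) and were called by camera (adjusted p = 0.0141), with an adjusted p = 0.241 with an estimated correlation, 0.0510 without KO replicate 1 and 0.0750 without WT replicate 2. With the cerebellum term their median was 0.25 (camera adjusted p = 0.0431). Cerebellar granule cell genes had a median of 0.42 (10 genes, camera adjusted p = 0.0947, and 4.01e-07 with the replicate block), and all of the difference between libraries described for Gabra6 applies to them. With an estimated correlation and no covariate, the camera adjusted p was 0.644 for inhibitory, 0.693 for striatal and 0.735 for granule cell genes. Immediate early genes had a median of -0.24 (10 genes) and were called by camera (adjusted p = 0.0274), with an adjusted p = 0.644 with an estimated correlation, 0.336 with the cerebellum term, 0.613 without KO replicate 1 and 0.767 without WT replicate 2. In these 7 lists edgeR called 0 genes, and with the replicate block 2 excitatory, 2 cholinergic, 2 granule cell and 1 immediate early gene. DESeq2 called 2, both excitatory neuron genes; adjusted over the list alone, 2 excitatory and 2 cholinergic genes were called. At an unadjusted p under 0.05 there were 2 excitatory, 2 cholinergic, 1 inhibitory and 1 immediate early gene.

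Of the remaining lists, the 12 genes of PRMT5 partners and Sm proteins, the spliceosome proteins that PRMT5 methylates, had a median of 0.20 and were called by camera (adjusted p = 0.00542), with an adjusted p = 0.246 with an estimated correlation. With length-adjusted offsets the adjusted p was 0.273, and without KO replicate 3 it was 0.0727. The integrated stress response (15 genes, median 0.05, camera adjusted p = 0.432), inhibitors of oligodendrocyte differentiation (12 genes, median 0.05, camera adjusted p = 0.750) and erythrocytes (5 genes, median -0.05, camera adjusted p = 0.531, and 0.0176 with length-adjusted offsets) were not called. EdgeR called 0 members of these 4 lists, and DESeq2 called 1, an inhibitor of differentiation. With the replicate block, and adjusted over the list alone, 1 stress response gene and 1 inhibitor were called, and 1, 2, 1 and 0 members had an unadjusted p under 0.05, in the order given.

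In the mm10 build, Prmt5 lies on chromosome 14 from 54507187 to 54517525 on the minus strand, and Mbp on chromosome 18 from 82475146 to 82585637 on the plus strand. Olig2 (91225457 to 91228677) and Olig1 (91269772 to 91271933) are neighbours on chromosome 16, both on the plus strand. Pdgfra spans 75152292 to 75198215 on chromosome 5, Sox10 79154908 to 79165240 on chromosome 15, Gpr17 31942997 to 31949636 on chromosome 18, and Col3a1 45311538 to 45349706 on chromosome 1. Counts are per gene, over its exons, and do not separate exons or isoforms.

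**Figure D3:**
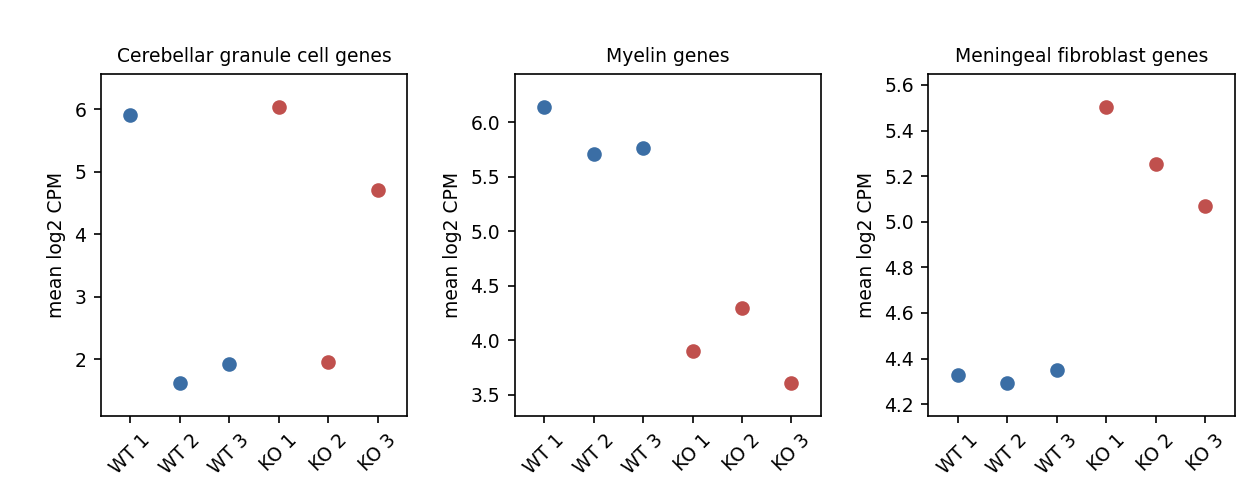
Mean log2 CPM (vertical axes, not starting at 0) of the cerebellar granule cell, myelin and meningeal fibroblast lists in each of the 6 libraries (WT blue, KO red). The granule cell mean is 5.91, 6.03 and 4.70 in WT 1, KO 1 and KO 3 and under 2 in the others, while the myelin mean is lower, and the meningeal mean higher, in all 3 KO libraries.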

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

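The fits that use the cerebellum term, the sex term, part of the libraries, GC content or exon length were chosen after the data were seen; all others were fixed beforehand. The lists of lineage transcription factors, precursors, newly formed oligodendrocytes, myelin genes and meningeal fibroblasts kept direction and call in every fit that tested them, except that myelin and meningeal genes each had an adjusted p of 0.0530 with an estimated correlation. Of 34 called genes that the naming rule took, 24 kept the call without each library in turn, as did 11 of 16 lists. Counts within 1.5-fold of 199 came from the other scalings, filters, limma fits, robust spread and thinning. Where no construction is named, the cause was not tested.

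DESeq2 called 315 genes (74 higher, 241 lower). The replicate block, whose pairing was taken from these same data, gave 566 (171 higher, 395 lower) with Prmt5 called at -0.33. Its changes to the calls of named genes and lists are given with each result. Block and cerebellum term together gave 535 (203 and 332, Prmt5 -0.41), block and GC offsets 606 (167 and 439, Prmt5 -0.35), and block and length offsets 476 (125 and 351, Prmt5 -0.34). Only pair 3 differs in cerebellar transcripts, so block and cerebellum term together take the genotype difference from pairs 1 and 2 alone. Fewer residual degrees of freedom remain in that fit than with the block alone. The sex term gave 129, with 15 higher, and ended the calls of Tbx18 (edgeR adjusted p, Benjamini-Hochberg, 0.0873), Tlr12 (0.0981), Hmgcs1 (0.0522), Cyp51 (0.104), C4b (0.0699), Vim (0.124), Enpp2 (0.108) and Trh (0.0942). Libraries without cerebellar transcripts gave 1254 (555 higher, 699 lower, 240 at least 2-fold), with Prmt5 at -0.415, Gfap at 0.629 (edgeR adjusted p, Benjamini-Hochberg, 8.62e-08) and Sall1 turned to 0.022; Prmt5, Slc1a2, Aurka, Emp1, Spp1, Cdkn1a and Apoe passed the threshold as well. Those with them gave 20 higher, Gfap turned to -0.17, and 12 genes of that rule lost their calls, among them Pdgfra (edgeR adjusted p, Benjamini-Hochberg, 0.0859), Olig1 (0.182), Hmgcs1 (0.796), C4b (1) and Vim (1). Each has 3 libraries, 1 of them alone in its group, so neither measures the spread within that group. Single calls were also lost for Enpp2 with upper-quartile factors or the 1 CPM filter, Cyp51 with library totals, Tlr12 and Trh with limma-voom, and Vim after thinning. Leaving out 1 library gave 100 to 305 genes, 9 to 44 higher and 91 to 261 lower, with 1 sample fewer.

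With an estimated correlation, camera's adjusted p was 0.0840 for cholesterol synthesis, 0.277 for proliferation, 0.153 for reactive astrocytes and 0.145 for activated microglia. Directional fry, which does not compare with other genes, gave 0.125, 0.0672 and 0.0672 for the latter 3. Mixed fry, which allows changes in either direction, gave 0.0127, 0.0101 and 0.00199 for them. Interferon response, PRMT5 partners, excitatory and cholinergic neurons and immediate early genes were not called by directional fry either. Mixed fry gave 0.0116, 0.0198, 0.372, 0.0613 and 0.69 for these, in the order given. Without a filter the p53 list was called (0.0402). Granule cells were called without a filter (0.0402), with the sex term (0.0320) and with GC offsets (0.0403). With the cerebellum term homeostatic microglia (0.0431), inhibitory neurons (0.00034), striatal neurons (3.81e-05) and choroid plexus (0.0111) were called, and the direction turned for astrocytes (0.832) and granule cells (0.336), as it did for sex-linked genes with the sex term (0.763). With length offsets activated microglia had 0.101 (0.0866 with the block). Among lists not called in the fit of all libraries without covariates, the direction turned with length offsets for homeostatic microglia (0.921, with the block 0.903), the stress response (0.891, 0.765), inhibitors of differentiation (0.627, 0.543) and arginine methyltransferases (0.955, 0.903). It also turned for the methyltransferases with GC offsets (0.749, with the block 0.688) and, for inhibitors and methyltransferases, with block and cerebellum term (0.864 and 0.872). Block and cerebellum term together also called granule cells, upward (0.0194), sex-linked genes (0.0116), erythrocytes (0.00369), inhibitory neurons (0.000673), striatal neurons (3.22e-05) and choroid plexus (0.000277), and ended the calls of PRMT5 partners (0.135), excitatory neurons (0.0599) and interferon response (0.302). These values rest on the genotype difference in pairs 1 and 2 alone.

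Leaving out 1 library turned the direction or gave a call at least once for these lists, none called in that fit, with these lowest and highest adjusted p: arginine methyltransferases 0.608 to 1, astrocytes 0.461 to 0.972, granule cells 1.1e-07 to 0.858, erythrocytes 0.0179 to 0.973, homeostatic microglia 0.0937 to 0.964, inhibitors of differentiation 0.453 to 0.923, p53 targets 0.00988 to 0.194, pan-neuronal genes 0.599 to 0.856, pericytes 0.183 to 1, choroid plexus 0.0127 to 0.608, inhibitory neurons 0.0122 to 0.599, and striatal neurons 0.00254 to 0.889.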

Other observations

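The 13 symbol families, the tests of proportional lineage loss and of meningeal share, and both tests on Olig2 and Olig1 were chosen after the results were seen. For the tests on scores, the criterion was also changed after their values were known, from 2 standard errors to a 95% interval with unequal variances.

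Some collagen genes were higher in KO. Of 43 tested collagen genes 10 rose, and the family was called by camera among 13 families (adjusted p = 5.07e-10), with an adjusted p = 0.174 with an estimated correlation. They included chains of fibrils, of basement membranes and of the transmembrane and multiplexin types (Col3a1, Col15a1, Col13a1). Among 11 laminin genes 10 had positive values and 1 rose (camera adjusted p = 0.000972, and adjusted p = 0.174 with an estimated correlation). Genes for cytosolic ribosomal proteins (74 of 79 positive, median 0.18) and for respiratory complex I (43 of 45 positive, median 0.18) were called by camera too, at adjusted p = 5.07e-10 and 3.37e-09, and at adjusted p = 0.299 for both with an estimated correlation. Camera also called mitochondrial ribosomal proteins (3.34e-06), insulin-like growth factor binding proteins (0.000972) and the proteasome (0.0156) higher, and semaphorins and plexins (0.00654, 4 of 29 fell) and potassium channels (0.0156) lower, none of them with an estimated correlation (lowest adjusted p = 0.174). With length-adjusted offsets the camera adjusted p was 0.539 and 0.823 for cytosolic ribosomal proteins and complex I, whose genes are short, and 3.90e-17 for collagens. It was 0.729 for mitochondrial ribosomal proteins, 0.539 for the proteasome, 0.539 for semaphorins and plexins, 0.0932 for potassium channels and 0.0713 for the binding proteins, so these calls ended too, while laminins stayed called (8.88e-07).

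Myelin genes fell further than precursor genes. The mean log2 CPM of precursor genes, leaving out Gpr17 and Neu4, minus that of myelin genes was higher in KO by 1.471 (SE 0.189, 95% interval 0.916 to 2.025). The exact permutation p was 0.1, the smallest that 3 against 3 samples allow. If both lists are expressed in the lineage alone, this argues against a loss of the whole lineage in 1 proportion. Precursor genes also expressed in other cells would fall less under such a loss, and this was not tested. Other values argue against the presence of cerebellum or gene length as the whole account. The myelin median was -2.085 with the cerebellum term, and -2.526 and -1.61 among libraries with and without cerebellar transcripts. Precursor (again without Gpr17 and Neu4) and myelin medians lay 1.837 apart with length-adjusted offsets, against 1.672 without. The cerebellum term marks presence and not amount. Gabra6 stood at 63.84 CPM in WT replicate 1, 80.03 in KO replicate 1 and 22.11 in KO replicate 3. Differences in amount among these libraries were not tested. The highest myelin median under the other scalings, -2.05, decides nothing here, since a scaling moves all genes of a library alike. Dissection differences other than the presence of cerebellum were not tested. A candidate explanation is that KO cells were held before or during differentiation, or that differentiated cells were lost, and these data do not separate the 2.

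Meningeal fibroblast genes rose together. Their median stayed at 0.736 with GC-adjusted offsets (6 of 9 called) and at 0.685 with the sex term (4 called), against 0.749, which argues against GC content or unequal sexes as the whole account. The 9 genes rose by unequal factors (Cochran's Q against a chi-square distribution, p = 1.48e-09, which takes the standard errors from 3 samples a group as known), but some, such as Igfbp2 and Igf2, are also expressed outside the meninges, so a larger share of meningeal tissue in the KO samples and a change within fibroblasts cannot be told apart. The higher medians of the hypothalamic (1.26) and ependymal (0.61) lists leave differences in dissection open as well.

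Olig2 and Olig1 fell by similar amounts. Olig2-Cre lines often carry Cre in place of 1 Olig2 allele, which would lower Olig2 by about 1 on the log2 scale beside Olig1. The KO minus WT difference of the log2 ratio of Olig2 to Olig1 was -0.188 (SE 0.116, 95% interval -0.513 to 0.137, exact permutation p = 0.2). This argues against the loss of the reads of 1 Olig2 allele in KO alone, on top of a fall shared with Olig1. It does not decide whether the line carries such an allele. That would require WT samples without Cre and an insertion that removes the counted Olig2 exons, and neither was tested. Olig1 and Olig2 against the other precursor markers differed by -0.347 (SE 0.160, 95% interval -1.026 to 0.331; exact permutation p = 0.1), and every KO value (at most 2.01) lay below every WT value (at least 2.02), but the interval holds 0, so fewer precursors and a lower level per cell cannot be told apart with 3 samples a group. Under the earlier criterion of 2 standard errors this value would have counted against fewer precursors as the whole account.

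The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split called 199 genes, 1 of the 10 with as many, and the highest other 73, the split that follows cerebellar transcripts. For genes lower in KO these values were 159 and 71 (1 of 10), and for genes called at least 2-fold 106 and 59 (1 of 10). For genes higher in KO they were 40 and 71 (2 of 10), the larger again from the split by cerebellar transcripts; with the cerebellum term 46 genes were higher. Of the 4 splits that part all 3 pairs, the real one called 566 genes with the replicate block (1 of 4) and each of the others 0, in edgeR's test, which called 0 in them without the block as well. Every split but the real one has WT and KO samples on both sides. A genotype difference would then widen the spread within sides and lower the calls.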
